A study of Arabidopsis thaliana with 16 samples.

How the data were processed

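RNA was measured in pollen tubes of Arabidopsis thaliana grown semi-in vivo, that is, tubes that grew through a cut pistil before collection. Plants were wild type or carried paps1-1, an allele of PAPS1 (AT1G17980), which encodes the nuclear poly(A) polymerase 1. The labels give the ecotype Col-0 for both genotypes. Per the labels' protocols, RNA was isolated with a column kit for very small samples, and each of 8 RNA samples was split into 1 library primed with oligo(dT) and 1 primed with random hexamers, with a step that removes ribosomal RNA in both. This gives 4 groups of 4 libraries, 16 libraries in all. The labels do not say whether replicates came from separate plants or days, so p-values measure only the spread between these samples, which may be technical.

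The values are read counts per gene that the authors deposited for each library. Per the submitters' processing notes, STAR was the aligner and TAIR10 the genome. The STAR version, the gene annotation release, and any trimming or removal of duplicate reads are not given in the sources used here. Each deposited table holds counts without regard to strand, counts on the strand of the gene and counts on the opposite strand for 33323 genes, all of them nuclear. Plastid and mitochondrial genes were not analysed here. The counts on the strand of the gene were used, since they exceeded those on the opposite strand in every library. The 4 rows that name no gene (unmapped, multimapping, no feature, ambiguous) were left out of library sizes and tests, and held between 55.1% and 99.6% of a library's reads. Gene names came from a RefSeq annotation of TAIR10.1, which matched 32835 of the identifiers. No coordinates were taken from it because its build differs from that of the counts, and genes are placed by chromosome and locus number.

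Gene counts ranged from 70006 to 5294720 per library, and the limit that a count of 0 allows (3 counts) ranged from 0.567 to 42.9 CPM (a gene's counts scaled to a library's total gene counts). Intervals and limits of this kind cover counting error only, since the reads carried no molecular identifiers. No pair of libraries in a group agreed within sampling noise, with a chi-square per degree of freedom of at least 20.5, so each library counted once.

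Counts were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, after TMM normalisation and filterByExpr (minimum count 10, minimum total count 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 genotype comparisons were each fitted on the 8 libraries of 1 priming method. The interaction and both priming comparisons came from 1 fit over 16 libraries with the RNA sample as a block. Standard errors are the log2 fold change divided by the square root of F. Group means of CPM were scaled by the TMM factors, and values of single libraries are CPM of that library's gene counts. Log2 CPM values used a prior count of 2. For a gene with no counts in a group, the fold is a lower bound that covers counting error only, not transcripts lost while a library was made. It was computed against the CPM of 3 counts in each library of that group, averaged over its libraries. For 1 to 3 counts in a group it is a ratio of counts pooled over each group, with its 95% counting interval. Lower bounds and ratios are therefore not directly comparable. Values of single measures were compared with exact two-sided permutation tests, for which 4 against 4 libraries cannot give a p below 0.0286.

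The lists held 15 groups of genes. They covered poly(A) polymerase and 3-prime end processing, cytoplasmic poly(A)-binding proteins, mRNA decay, pollen-tube receptors and signalling, pollen cell wall, pollen actin, pollen sugar and proton transport, pollen transcription factors, sperm cells, pistil, photosynthesis, heat shock and protein folding, immune response, cytosolic ribosomal proteins and SAUR genes. They were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry). The ribosomal rule was narrowed to genes annotated as ribosomal proteins, because the rule first written also took disease-resistance genes with similar symbols. This change was made after the genotype comparisons had been run and values of single genes had been seen, and before the lists were tested. A locus entered among the receptors as MIK1 is annotated as HAESA and was kept.

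The design, the alternatives, the rule for named genes and, apart from that change, the lists were fixed before the data were examined. That rule takes, in the genotype comparisons and the interaction, genes past the threshold with a mean log2 CPM of at least 3 and no overlap between groups, up to 10 in each direction (5 in the priming comparisons). Where none passed, it takes the 5 of smallest p in each direction. It adds the 4 PAPS genes and up to 4 members of each list with the smallest p. Where few genes passed the threshold, the others were named after their values were seen.

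Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, other count filters, counts without regard to strand, a 2-fold minimum, a replicate block or none, TMM within each priming method, limma voom with duplicateCorrelation, and each replicate left out in turn. Leaving out particular libraries (among them those of paps1-1 RNA samples 2 and 3, chosen for their low pollen and high ribosomal protein shares), a minimum of 10 counts in every library, and robust empirical Bayes were added after the data were seen. The fits were tested on simulated counts built from real library sizes, the fitted spread and real means pooled over the genotypes, with 200 genes changed. For the priming tests the means were pooled over all libraries, so only the changed genes held a priming effect, unlike the data. The simulated means held no effect of RNA sample, and no loss of transcripts beyond the fitted spread was simulated. At that spread, the random-hexamer genotype test recovered 8.93%, 63.5% and 92.6% of 4-fold, 16-fold and 64-fold changes among 10590 genes. The oligo(dT) genotype test recovered 0%, 0% and 25% among 3411 genes, and the interaction test recovered none of any size among 12587 genes. Of 64-fold changes, the priming tests recovered 10.5% among 13208 genes in wild type and 6.56% among 13238 genes in paps1-1. With a biological coefficient of variation of 0.3 at the same library sizes, the oligo(dT) genotype test recovered 98.5%, 100% and 100% among 5100 genes, the random-hexamer genotype test 97.0%, 100% and 100% among 12298 genes, and the interaction test 58.5%, 93.8% and 95.3% among 13895 genes. The priming tests then recovered 86.2%, 100% and 100% in wild type among 13778 genes and 95.5%, 100% and 100% in paps1-1 among 13882 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.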

Results

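The series measured transcripts in Arabidopsis pollen tubes of the paps1-1 mutant, which lacks full function of the nuclear poly(A) polymerase PAPS1, and in wild-type tubes. Its title gives the purpose of the paired libraries, an estimate of poly(A)-tail length from transcripts primed with oligo(dT) and with random hexamers. Each of the 4 groups held 4 libraries. Gene counts averaged 1225680 ± 1219430 (SD, n = 4) in wild-type oligo(dT) libraries, 2166910 ± 1875750 in paps1-1 oligo(dT) libraries, 2378270 ± 1409730 in wild-type random-hexamer libraries and 2768060 ± 2000260 in paps1-1 random-hexamer libraries.

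Oligo(dT) libraries detected fewer genes than the random-hexamer libraries of the same RNA in 8 of 8 pairs, with a mean difference of -6985 genes (exact two-sided permutation p = 0.00781). Unmapped reads were 82.1% ± 13.2 (SD, n = 4) of reads in wild-type and 77.5% ± 12.4 in paps1-1 oligo(dT) libraries, against 38.8% ± 28.8 and 29.6% ± 9.76 in the random-hexamer libraries. VGD1 (AT2G47040), a pollen pectin methylesterase, held the most counts of any gene in each oligo(dT) library. Wild-type oligo(dT) replicate 3 held 70006 gene counts and 2266 detected genes. In it, 1600 of 2240 genes that were abundant in other libraries had no count, where about 13.3 would be at 0 from sampling alone. Zeros beyond sampling were not confined to this library. Such genes made up 13.4%, 12.5% and 8.36% in wild-type oligo(dT) replicates 1, 2 and 4. In paps1-1 oligo(dT) replicates 1 to 4 they made up 0.859%, 0.626%, 25.4% and 27.0%, and in wild-type random-hexamer replicate 3 18.0%. Sampling alone would leave almost none at 0 in these libraries. Replicates of 1 group correlated with a median Spearman rho across genes of 0.303 and 0.373 in wild-type and paps1-1 oligo(dT) libraries, and of 0.582 and 0.764 in random-hexamer libraries.

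**Figure D1:**
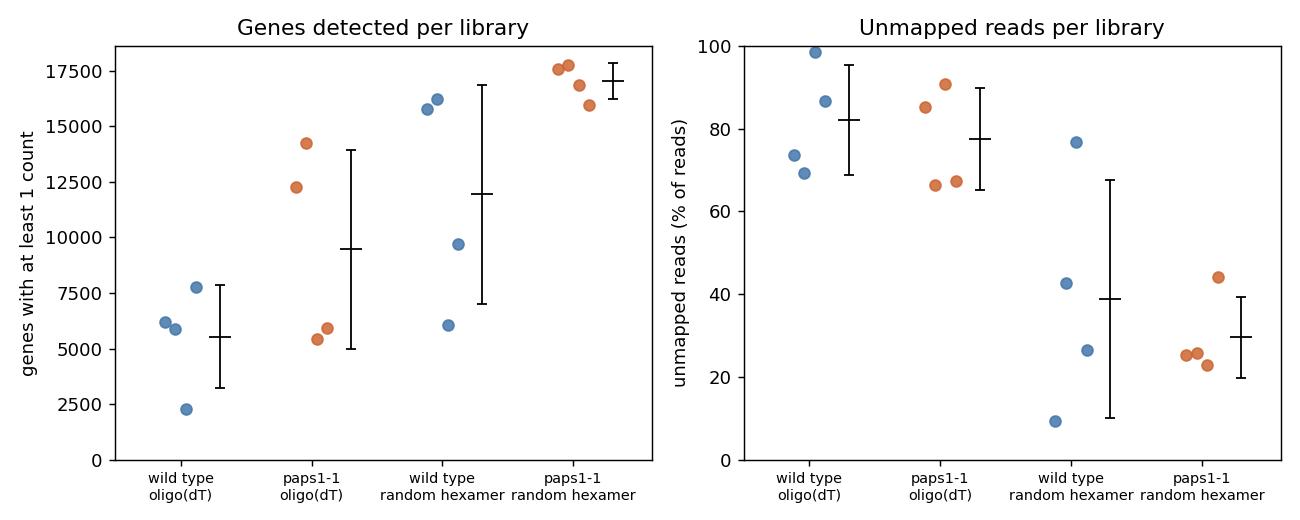
Genes with at least 1 count (left) and unmapped reads as a percentage of reads (right) in each library, grouped by genotype and priming method, with points for libraries and bars for the mean and SD (n = 4). Mean genes detected were 5528 and 9459 in wild-type and paps1-1 oligo(dT) libraries, and 11936 and 17021.5 in random-hexamer libraries.

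PAPS1 (AT1G17980, chromosome 1) was detected in each library but wild-type oligo(dT) replicate 3. It stood at 47.3, 64.2, 308 and 79.1 CPM of gene counts in the paps1-1 oligo(dT) libraries and 284, 47.0, 0 and 58.6 CPM in the wild-type ones. In the random-hexamer libraries it stood at 142, 72.9, 77.3 and 217 CPM in paps1-1 and 141, 102, 126 and 216 CPM in wild type. Its log2 fold change between genotypes was -0.06 ± 1.77 (SE) with oligo(dT) and -0.16 ± 0.65 with random hexamers (edgeR adjusted p = 1.00 in both). No direction can be given, since it was 1.08 with oligo(dT) under DESeq2 size factors and 0.50 with random hexamers without paps1-1 replicates 2 and 3. The paps1-1 allele is a point mutation that changes the protein, so the transcript level does not check the labels. PAPS2 (AT2G25850), PAPS3 (AT3G06560) and PAPS4 (AT4G32850, nPAP) did not pass the threshold between genotypes either, with log2 fold changes of -0.10, -0.55 and 0.24 with random hexamers.

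The genotypes were first compared in the random-hexamer libraries, which measure transcripts without selecting for a poly(A) tail. Most of the 9 genes past the threshold were close to all-or-none. AT3G43550 and AT3G43570, neighbouring GDSL-type lipase genes on chromosome 3, averaged 229 ± 230 and 168 ± 157 CPM (SD, n = 4) in wild type, with a single count each over the 4 paps1-1 libraries. Their wild-type to paps1-1 ratios were 2373 (95% counting interval 425 to 93777) and 1629 (292 to 64406). These paralogs lie close together, and the counting could split reads between them. AT3G43681, an uncharacterised gene of the same part of chromosome 3, went the other way, at 169 ± 132 CPM in paps1-1 with no count in wild type, at least 83.8-fold higher. The nearby AT3G43675 was likewise at least 31.9-fold higher in paps1-1, at 64.6 ± 52.7 CPM.

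On chromosome 1, BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum induced by unfolded proteins, averaged 4.33 ± 5.14 CPM in paps1-1 and 208 ± 185 CPM in wild type (SD, n = 4). Its log2 fold change was -5.53 ± 1.09 (SE, edgeR adjusted p = 0.0354). The uncharacterised AT1G35115 averaged 6.58 ± 7.50 CPM against 280 ± 115 CPM, with a log2 fold change of -5.52. AT1G31990 had no count in paps1-1 and was at least 32.4-fold lower, and AT3G32925 had 2 counts there, with a wild-type to paps1-1 ratio of 300 (82.6 to 2485). FAF1 (AT4G02810) averaged 2.39 ± 2.30 CPM against 733 ± 1362 CPM, with groups that overlapped. AT1G31990, AT3G32925, AT3G43675 and FAF1 fell outside the rule for named genes and were chosen after their values were seen.

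In all, 2 genes were higher and 7 lower in paps1-1 among 12595 tested with random hexamers. The calls of AT3G43681, AT3G43550 and AT3G43570 held without any single library. BIP3 and AT1G35115 no longer passed without wild-type replicate 1, 2 or 3 (adjusted p from 0.0899 to 0.610), AT1G31990 without these or paps1-1 replicate 1 or 2 (0.0899 to 0.387), and AT3G32925 without wild-type replicate 1 or 2 or paps1-1 replicate 1, 2 or 3 (0.0833 to 0.387). With any 1 replicate left out log2 fold changes stayed between -6.37 and -4.77 (BIP3), -6.37 and -4.81 (AT1G35115), -10.33 and -9.14 (AT1G31990), -8.62 and -7.23 (AT3G32925) and 9.45 and 10.49 (AT3G43675). AT3G43675 did not pass without wild-type replicate 1 or 2 or paps1-1 replicate 1 (0.0507 to 0.391), nor with counts taken without regard to strand (log2 fold change 3.90). FAF1 had a log2 fold change of -8.46, which moved to -4.62 without wild-type replicate 3 (adjusted p = 1.00), and it did not pass without paps1-1 replicate 1 (0.0638). Without wild-type replicate 1, 2 or 3 the count of genes was 5, 4 and 5. Without paps1-1 replicates 2 and 3 together it was 9, of which 5 were shared, and BIP3, AT1G35115, AT1G31990 and AT3G32925 did not pass (adjusted p from 0.0515 to 0.416). The DESeq2 Wald test called 25 genes higher and 12 lower, 8 of the 9 among them.

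**Figure D2:**
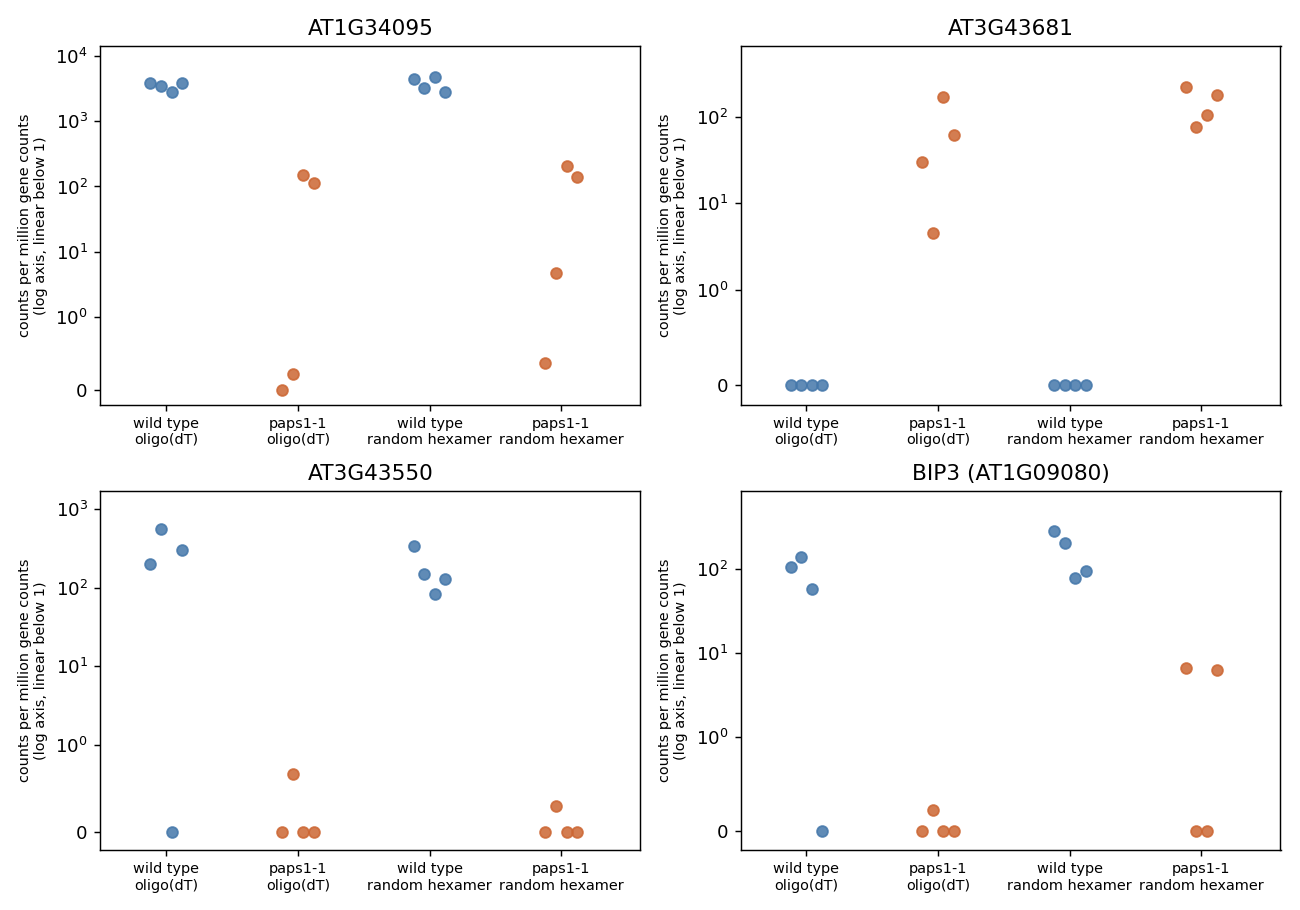
CPM of gene counts (log axis, linear below 1) of 4 genes called between genotypes, with 1 point per library, grouped by genotype and priming method. AT3G43681 has no count in any wild-type library, while AT1G34095 lies at 2737 or above in each wild-type library and at 205 or below in each paps1-1 library.

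Heat shock and protein-folding transcripts had lower values in paps1-1 with random hexamers. All 14 measured members had a negative log2 fold change, with a median of -1.59. Of these, 1 (BIP3) passed the threshold over all genes and 5 when adjusted over the list alone. The 5 became 1 without paps1-1 replicate 2 or 4 or wild-type replicate 1 or 2, 2 without paps1-1 replicate 3, and 8 without paps1-1 replicate 1 or with DESeq2 size factors. HSP90.1 (AT5G52640), a cytosolic chaperone, averaged 1236 ± 568 CPM in paps1-1 and 5307 ± 2532 CPM in wild type (SD, n = 4). HSP101 (AT1G74310), a chaperone that dissolves protein aggregates, averaged 425 ± 139 against 1344 ± 592 CPM. HSFA2 (AT2G26150), a heat shock transcription factor, averaged 20.9 ± 10.9 against 117 ± 78.0 CPM, and the small heat shock protein gene AT1G07400 averaged 171 ± 69.5 against 538 ± 257 CPM. HSP101 was named after its values were seen. Together the list took 0.480% ± 0.0588 of gene counts in paps1-1 and 1.39% ± 0.269 in wild type (exact two-sided permutation p = 0.0286, the smallest possible, and 0.214 adjusted over 15 lists). The mean log2 CPM of its members was 6.76 ± 0.764 in paps1-1 and 8.30 ± 1.17 in wild type (exact two-sided permutation p = 0.114, and 0.343 adjusted), and the groups overlapped, with wild-type replicate 4 at 7.17 below paps1-1 replicates 1 and 4 at 7.37 and 7.38. Camera gave an adjusted p of 5.21e-14 with the preset correlation and an adjusted p = 0.347 with an estimated correlation, and fry an adjusted p of 0.231.

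**Figure D3:**
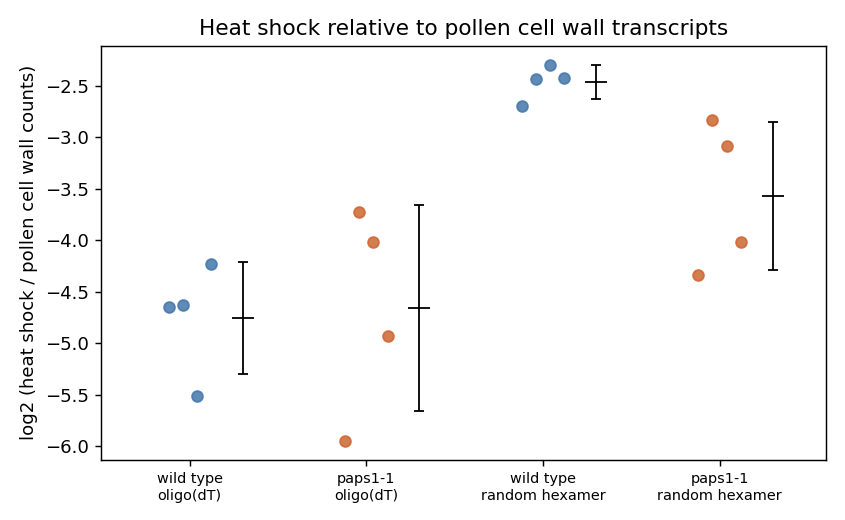
Log2 ratio of summed heat shock list counts to summed pollen cell wall list counts within each library, with points for libraries and bars for the mean and SD (n = 4). With random hexamers the ratio averaged -3.57 in paps1-1 and -2.46 in wild type without overlap, and with oligo(dT) the groups overlapped at -4.66 and -4.76.

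Genes of pollen-tube function were described by 5 lists, and no member of any passed the threshold between genotypes with random hexamers. Receptors and signalling genes had 32 of 38 negative values (camera adjusted p = 2.82e-09), cell wall genes 14 of 17 (8.34e-05), transcription factors 9 of 10 (0.00123), actin genes 8 of 13 (0.00282) and sugar and proton transport genes 4 of 6 (0.00278). With an estimated correlation each of these was lost, with an adjusted p = 0.547 for transport and an adjusted p = 0.576 for the others. These lists were low in 2 of the 4 paps1-1 libraries. Receptor genes took 0.977% and 0.863% of gene counts in paps1-1 replicates 2 and 3, 2.34% and 2.15% in replicates 1 and 4, and 1.93% to 2.51% in wild type. Cell wall genes took 3.84% and 3.47%, 9.26% and 8.34%, and 5.92% to 9.60%, and the transport, transcription factor and actin lists also had their smallest shares in replicates 2 and 3. Pistil markers took 0.0456% in paps1-1 replicate 2, 0.0120% to 0.0129% in the other paps1-1 libraries and 0.00486% to 0.0138% in wild type. Photosynthesis genes took 0.790% in paps1-1 replicate 3 and 0.0331% to 0.270% in the other random-hexamer libraries. Without paps1-1 replicates 2 and 3, which were chosen for their low pollen and high ribosomal protein shares, none of the 5 lists passed (camera adjusted p from 0.897 to 0.955), and 27 of 38 receptor values were positive. The loss of these calls follows in part from that choice. ROPGEF8 (AT3G24620), an activator of ROP GTPase signalling, averaged 95.5 ± 79.9 CPM in paps1-1 and 262 ± 111 CPM in wild type. WRKY2 (AT5G56270), a pollen transcription factor, averaged 142 ± 84.97 against 370 ± 174 CPM, and CALS5 (AT2G13680), a callose synthase, 874 ± 668 against 1590 ± 589 CPM. Cytoplasmic poly(A)-binding proteins had 5 of 7 negative values (camera adjusted p = 0.0130, adjusted p = 0.347 with an estimated correlation, and camera adjusted p = 0.505 without replicates 2 and 3). Of these, the pollen-expressed PAB5 (AT1G71770) averaged 266 ± 180 against 650 ± 337 CPM.

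Cytosolic ribosomal protein genes had 200 of 230 positive values with random hexamers, a median log2 fold change of 0.71, and no member past the threshold (camera adjusted p = 0.00797, and adjusted p = 0.810 with an estimated correlation). Over all genes the median was 0.38, and 0.53 with DESeq2 size factors. The list took 1.91% and 2.05% of gene counts in paps1-1 replicates 2 and 3, 0.453% and 0.796% in replicates 1 and 4, and 0.287% to 1.19% in wild type. The highest pistil share was that of paps1-1 replicate 2, and the highest photosynthesis share that of paps1-1 replicate 3. Without replicates 2 and 3 its median was 0.19, with 138 of 238 values positive (camera adjusted p = 0.948). These replicates were chosen in part for their high ribosomal protein shares, so this loss follows in part from the choice. STV1 (AT3G53020), a protein of the large subunit, averaged 124 ± 33.2 CPM in paps1-1 and 26.0 ± 31.3 CPM in wild type. Of the 3-prime end processing genes 19 of 26 were positive, and of the mRNA decay genes 19 of 24, neither list past the threshold (adjusted p = 0.838 for both). DCP5 (AT1G26110), a decapping factor, averaged 98.3 ± 39.3 against 36.7 ± 25.9 CPM without passing the threshold. Lists of sperm cell (2 of 4 positive), pistil (4 of 6), photosynthesis (16 of 20), immune response (3 of 3) and SAUR genes (2 of 7) did not pass either, with adjusted p of 0.838, 0.838, 0.0981, 0.806 and 0.497. The photosynthesis list ranked below other genes in camera although its median was positive. Without paps1-1 replicates 2 and 3 it had 18 of 22 negative values (camera adjusted p = 1.69e-05, and adjusted p = 0.981 with an estimated correlation). STK (AT4G09960), an ovule identity gene, averaged 90.7 ± 81.2 CPM in paps1-1 and 15.8 ± 12.1 CPM in wild type without passing the threshold.

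In the oligo(dT) libraries, which measure polyadenylated transcripts, a single gene passed the threshold between genotypes among 5101 tested. AT1G34095, an uncharacterised gene of chromosome 1, averaged 67.2 ± 77.4 CPM in paps1-1 and 4284 ± 1587 CPM in wild type (SD, n = 4). Its log2 fold change was -6.00 ± 1.24 (SE, edgeR adjusted p = 0.00693), and with random hexamers it was -5.80 ± 1.21 (adjusted p = 0.0565). It no longer passed with oligo(dT) without paps1-1 replicate 2 or 4, or without wild-type replicate 1, 2 or 4, where its adjusted p lay between 0.140 and 0.381 while its log2 fold change stayed between -6.62 and -5.60. Without paps1-1 replicates 2 and 3 together no gene passed in the edgeR test, with 291 at an unadjusted p under 0.05, and AT1G34095 had a log2 fold change of -6.05. In this comparison 86 genes had an unadjusted p under 0.05, fewer than the 255 expected if no gene differed. DESeq2 size factors gave 4 genes higher and 3 lower, and the DESeq2 Wald test 52 higher and 2 lower.

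Ribosomal protein genes were the list that camera called between genotypes with oligo(dT), with 152 of 169 values positive, a median of 1.44 and no member past the threshold (adjusted p = 7.14e-08, and adjusted p = 0.726 with an estimated correlation). The median over all genes was 0.43, and 0.81 with DESeq2 size factors. The list took 4.31% and 4.26% of gene counts in paps1-1 replicates 2 and 3, 1.08% and 1.53% in replicates 1 and 4, and 0.461% to 2.14% in wild type. Without replicates 2 and 3, chosen in part for their high ribosomal protein shares, it had 126 of 197 positive values (camera adjusted p = 0.759). That loss follows in part from the choice. Photosynthesis genes took 1.29% in paps1-1 replicate 3 and 0.00571% to 0.380% in the other oligo(dT) libraries. AT3G16080, a protein of the large subunit, averaged 180 ± 129 CPM in paps1-1 with no count in wild type. Pistil markers took 0.0294% ± 0.0222 of gene counts in paps1-1 and 0.00704% ± 0.00486 in wild type (exact two-sided permutation p = 0.0286, and 0.279 adjusted over 13 lists). Replicate 2 of paps1-1 stood at 0.0621%, and without it the paps1-1 mean was 0.0185% ± 0.00527 (SD, n = 3). The exact permutation p was 0.0857 without any 1 wild-type library and stayed at 0.0286 without any 1 paps1-1 library. Heat shock genes had 8 of 11 negative values and photosynthesis genes 15 of 15 positive values, with camera adjusted p of 0.0564 and 0.0597. HSP90.1 averaged 462 ± 267 CPM in paps1-1 and 1282 ± 664 CPM in wild type. Together the heat shock genes took 0.288% ± 0.0883 of gene counts in paps1-1 and 0.479% ± 0.115 in wild type (exact two-sided permutation p = 0.0571, and 0.279 adjusted over 13 lists). Cell wall genes took 7.84% ± 4.31 against 12.7% ± 2.14 (exact two-sided permutation p = 0.0857, and 0.279 adjusted), at 5.53% and 3.99% in paps1-1 replicates 2 and 3. The other 10 lists tested had adjusted p between 0.0564 and 0.678, and the sperm cell and immune lists held 1 measured gene each and were not tested.

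Genotype effects measured with the 2 priming methods had a Pearson r of 0.322 across 4838 genes, which are not independent replicates. Both libraries of a pair come from the same RNA, so a correlation above 0 arises without a genotype effect. Without wild-type replicate 1 the correlation was 0.116. None of the genes called between genotypes lay among locus numbers AT1G12000 to AT1G24000 around PAPS1 (0 of 9 and 0 of 1, two-sided Fisher's exact p = 1 for each).

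The interaction asks whether the ratio of oligo(dT) to random-hexamer transcripts differed between genotypes, the quantity the series title ties to poly(A)-tail length. No gene passed the threshold in the edgeR quasi-likelihood test among 14190 tested. An unadjusted p under 0.05 was found for 231 genes, fewer than the 709.5 expected if no gene differed. AT1G76010, an Alba-type RNA-binding protein gene, had the smallest p without passing. It had no count in any wild-type oligo(dT) library, 53.5, 45.7, 301 and 139 CPM in the paps1-1 ones, and between 25.4 and 199 CPM in the random-hexamer libraries. NUDT21 (AT1G73540), a nudix hydrolase, and BRI1 (AT4G39400), the brassinosteroid receptor, also had no count in the wild-type oligo(dT) libraries. The fitted ratio of such genes depends on the prior count. The U1 snRNA gene U1.5 (AT1G08115) had a log2 ratio change of -8.72 ± 2.70 (SE), without passing.

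The DESeq2 Wald test called 39 genes for the interaction, 18 higher and 21 lower, and limma voom called none. DESeq2 size factors gave 4, and leaving out wild-type replicate 3 gave 2. The median SE over genes was 4.09 on the log2 scale, and simulated changes of up to 64-fold were not detected at this depth and spread. With a biological coefficient of variation of 0.3 at the same library sizes, 58.5%, 93.8% and 95.3% of simulated 4-fold, 16-fold and 64-fold changes were detected. Photosynthesis genes had 17 of 23 positive interaction values and ribosomal protein genes 179 of 262 (camera adjusted p = 0.0188 and 0.0182), at a median over all genes of 0.97. Both were lost with an estimated correlation, each at an adjusted p = 0.947. Heat shock genes had 11 of 14 positive values (adjusted p = 0.240), and the other 12 lists did not pass.

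Oligo(dT) priming was then compared with random hexamers within wild type, to show which transcripts each favours. Past the threshold, 6 genes were higher and 157 lower with oligo(dT) among 14190 tested, while the median log2 ratio over all genes was -3.92. The 18S ribosomal RNA genes AT3G41768 and AT2G01010 were both lower, as 2 of 4 ribosomal RNA genes tested. NUDT21 had no count in the oligo(dT) libraries and averaged 300.4 ± 296 CPM with random hexamers (SD, n = 4), at least 59.9-fold lower. AT5G40450, HAC1 (AT1G79000), a histone acetyltransferase, EXO70C1 (AT5G13150), an exocyst subunit, and AT5G09880 were at least 42.8-fold, 33.5-fold, 38.0-fold and 37.5-fold lower. VGD1 was higher at 58058 ± 24463 against 23309 ± 12631 CPM, and AT3G04700 at 434 ± 287 against 3.06 ± 5.88 CPM.

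Pollen genes stood on both sides of this contrast in wild type. Of 17 cell wall genes, 2 were higher and 7 lower with oligo(dT), among them AGP23 (AT3G57690), an arabinogalactan peptide, with a log2 ratio of 3.35 ± 0.68 (SE) and the leucine-rich repeat extensin gene AT3G19020 with -3.86 ± 0.53. The pollen-tube transcription factor MYB120 (AT5G55020) had -7.29 ± 1.23, the potassium channel SPIK (AT2G25600) -7.09 ± 1.73 and HSP70 (AT3G12580) -4.40 ± 0.93. Receptor genes ranked lower as a list (32 of 37 negative, 4 called, camera adjusted p = 0.0140), and ribosomal protein genes ranked higher than other genes (camera adjusted p = 0.0140) although 186 of 262 values were negative and 1 was called lower. Both were lost with an estimated correlation at an adjusted p = 0.750.

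The count of genes called in wild type moved with the scaling and with single libraries. DESeq2 size factors gave 17 higher and 88 lower, and TMM within each priming method 8 higher and 52 lower. Among 204 genes with at least 10 counts in every library, which leaves out genes absent with oligo(dT), 38 were higher and 35 lower at a median of 0.03, with 20 of these calls shared with the 163. Without paps1-1 replicates 2 and 3 together 2 were higher and 50 lower, all of them shared. Leaving out wild-type replicate 1, 2 or 4 gave 67, 32 and 41 genes, and leaving out paps1-1 replicate 1 or 2 gave 101 and 76. NUDT21, AT5G40450, HAC1, EXO70C1 and AT5G09880 did not pass without wild-type replicate 1 or 2, with adjusted p from 0.0610 to 0.403. With any 1 replicate left out, the fitted log2 ratios stayed within -12.48 to -11.08, -11.54 to -11.00, -11.59 to -10.90, -11.60 to -10.47 and -11.48 to -10.66. The last 4 did not pass without replicate 4 either, nor EXO70C1 without paps1-1 replicate 1. VGD1 did not pass without paps1-1 replicate 2, 3 or 4 (adjusted p from 0.0534 to 0.0888), where its log2 ratio lay between 1.35 and 1.48. AT3G04700 kept its call without any single library.

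In paps1-1 the same contrast called 4 genes higher and 36 lower with oligo(dT), at a median log2 ratio over all genes of -2.53. AGP23 was higher, at 22491 ± 27012 against 821 ± 706 CPM (SD, n = 4), with a log2 ratio of 4.53 ± 0.61 (SE), and kept its call without any single library, but not without paps1-1 replicates 2 and 3 together (adjusted p = 0.226). AT3G04700, AT4G14315 and AT2G35765 were also higher, the last at 6693 ± 7643 against 668 ± 477 CPM. AT2G20440, AT1G79640, AT4G16680 and AT5G41780 had no count in the oligo(dT) libraries and were at least 80.1-fold, 75.7-fold, 60.6-fold and 55.7-fold lower. These bounds too cover counting error only, while 0.626% to 27.0% of genes abundant in other libraries had no count in the paps1-1 oligo(dT) libraries. AT2G05390 had 1 count there, with a random-hexamer to oligo(dT) ratio of 4154 (745 to 164098). MYB120 was lower with a log2 ratio of -7.32 ± 1.30, SPIK with -6.76 ± 1.60 and HSP70 with -4.86 ± 0.95. Ribosomal protein genes ranked higher than other genes (camera adjusted p = 3.67e-11, and adjusted p = 0.763 with an estimated correlation), with 121 of 262 values positive and none called.

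Wild type and paps1-1 shared 3 higher and 30 lower genes between priming methods, where independent lists would share 0.00169 and 0.398. Both contrasts come from 1 fit and share its estimate of the spread. In paps1-1, DESeq2 size factors gave 17 higher and 44 lower genes, and TMM within each priming method 12 higher and 17 lower. Among genes with at least 10 counts in every library 33 were higher and 42 lower at a median of -0.21, with 11 of these calls shared with the 40. Without paps1-1 replicates 2 and 3 together 2 genes were lower, both shared. Leaving out wild-type replicate 3 gave 215 genes, and leaving out paps1-1 replicate 2, 3 or 4 gave 21, 16 and 19. AT3G04700, AT4G14315, AT2G35765 and AT2G05390 did not pass without paps1-1 replicate 1 or 2, nor AT2G35765 without replicate 3. The fitted log2 ratios of AT3G04700, AT4G14315 and AT2G35765 stayed within 8.81 to 12.56, 5.96 to 8.32 and 2.84 to 3.53 with any 1 replicate left out. AT2G20440, AT1G79640, AT4G16680 and AT5G41780 did not pass without any of the 4 paps1-1 replicates in turn or without wild-type replicate 2, with adjusted p from 0.0556 to 0.521. With any 1 replicate left out, their fitted log2 ratios stayed within -10.93 to -10.08, -10.77 to -9.95, -10.61 to -9.91 and -10.50 to -9.71, and that of AT2G05390 within -12.09 to -9.38. Without wild-type replicate 4, AT2G20440, AT4G16680 and AT5G41780 had adjusted p of 0.0887, 0.0519 and 0.0771.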

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

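The measures and genes described here were picked out because 1 library stood far from the others of its group, because camera called a list for the interaction of genotype and priming, or because a signal appeared in counts that the comparisons did not use, and apart from other splits of the samples no test of an explanation was run for them. A library was picked out where its gap to the nearest other library of its group took up most of the group's range. Of 159 groups of 4 libraries examined in this way 17 held such a library, where independent, normally distributed values would give about 7.95. Those assumptions are not met, since many measures come from the same libraries and some genes had counts in 1 library of a group only. Whether 17 exceeds chance is therefore not known.

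Wild-type RNA sample 3 stood apart in several measures. In its oligo(dT) library 71.4% of genes abundant in other libraries had no count, against 8.36% to 13.4% in the other wild-type oligo(dT) libraries, and in its random-hexamer library 18.0%, against 0.0358% to 2.06%. Ribosomal RNA genes took 0.180% of gene counts in the oligo(dT) library, against 0.00320% to 0.0132%. The mean log2 CPM of the mRNA decay list was 1.08 there, against 4.01 to 4.54, and that of the heat shock list 4.03, against 7.94 to 8.67. In paps1-1, oligo(dT) replicate 4 had 80.1% of its gene-assigned counts on the strand of the gene, against 94.4% to 95.2%, and random-hexamer replicate 4 had 44.1% unmapped reads, against 22.9% to 25.9%.

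Photosynthesis genes had a mean log2 CPM of 7.73 in paps1-1 random-hexamer replicate 3, against 4.02 to 4.54 in the other libraries of its group, and of 6.31 in wild-type random-hexamer replicate 4, against 4.09 to 4.46. SAUR genes had 5.77 in paps1-1 random-hexamer replicate 1, against 4.73 to 4.82. PAPS1 stood at 308 CPM in paps1-1 oligo(dT) replicate 3, against 47.3 to 79.1 CPM. AT3G04700 stood at 5.17 CPM in wild-type random-hexamer replicate 1, against 0 to 0.253 CPM, and AT5G09880 at 208 CPM in paps1-1 random-hexamer replicate 3, against 76.1 to 90.5 CPM. In oligo(dT) libraries, EXO70C1 had 2.42 CPM in paps1-1 replicate 1 with none in the others of its group. AT2G05390 had 36.0 CPM in wild-type replicate 1, against 0 to 1.13 CPM, and AT4G16680 had 46.2 CPM in the same library with none in the others. AT5G41780 had 58.6 CPM in wild-type replicate 4, against 0 to 1.00 CPM.

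For the interaction, photosynthesis genes and ribosomal protein genes had 17 of 23 and 179 of 262 positive values (camera adjusted p = 0.0188 and 0.0182 with the preset correlation). No member passed, neither call held with an estimated correlation (adjusted p = 0.947), and 8 of 35 splits of the samples called as many lists. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.871 for both. A difference between genotypes in the response to priming is therefore not shown. Counts on the strand opposite to the genes were not used in the comparisons. Tested in the same way, they gave 1 gene between genotypes with oligo(dT), AT3G45095, lower in paps1-1 among 282 tested. With random hexamers they gave 6 genes among 541 tested, 3 higher and 3 lower, namely AT1G35112, AT3G28153, AT3G41762, AT3G43680, AT3G45095 and AT5G09700. None of these was among the genes called on the gene strand. However, AT3G43680 and AT1G35112 lie close by locus number to AT3G43681 and AT1G35115, which were called there. Whether these are separate signals was not tested.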

How the results depend on the processing

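Leaving out named libraries together, a minimum of 10 counts in every library and robust empirical Bayes were chosen after the results were seen. Among single genes, 449 values stayed on their side of the threshold, 122 lost their call in the same direction and 2, both of PAPS1, moved. No called gene changed direction. PAPS1, which passed no test, changed sign. With oligo(dT) (-0.06) it was 1.08 with DESeq2 size factors, 1.06 in the DESeq2 Wald test, 0.72 with a replicate block, 0.02 with the stricter filter and -0.63 to 1.61 with 1 replicate left out. With random hexamers (-0.16) it was 0.50 without paps1-1 2 and 3 and -0.56 to 0.17 with 1 replicate left out. Its interaction (1.41) was -0.38 with no replicate block. Where a count moved the cause was not tested, except that fewer genes or samples entered the fits with stricter filters or left-out libraries.

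Counts are given as genotype with oligo(dT), genotype with random hexamers, interaction, priming in wild type and priming in paps1-1, whose values were 1, 9, 0, 163 and 40. With DESeq2 size factors the first moved to 7 and the last 3 to 4, 105 and 61. The DESeq2 Wald test gave 54, 37, 39, 1821 and 982. Without a filter on low counts the first 2 were 2 and 47 and priming in wild type 87. At least 50 counts in at least 4 libraries gave 4 for genotype with random hexamers, 270 for priming in wild type and 86 in paps1-1. Counts without regard to strand gave 2 for genotype with oligo(dT). TMM within each priming method gave 60 for priming in wild type. Limma voom gave 1684 and 2208 for priming. Robust empirical Bayes gave 50 and 18 for priming. At least 10 counts in every library gave 1 gene for genotype with random hexamers, with none shared. That filter leaves out genes with few or no counts in 1 genotype, such as most of the 9, so it does not test their calls. For priming it gave 73 (38 higher, 35 lower) and 75 (33 higher, 42 lower), where 204 genes were tested. The main fit gave 6 higher and 157 lower, and 4 higher and 36 lower. Without wild-type 3 and paps1-1 4, genotype with oligo(dT) gave 0 (387 at an unadjusted p under 0.05, edgeR), the interaction 3 and priming 380 and 168. Without wild-type 3 and 4, genotype with random hexamers gave 5. Without paps1-1 2 and 3, genotype with oligo(dT) gave 0 (291 at an unadjusted p under 0.05, edgeR) and priming 52 and 2. Leaving out 1 replicate at a time gave 0 to 3, 4 to 11, 0 to 2, 32 to 242 and 16 to 215. Genotype with oligo(dT) gave 0 without paps1-1 2, paps1-1 4, wild-type 1 or wild-type 4 (104 to 836 at an unadjusted p under 0.05), 1 higher gene without wild-type 2, and 3 without wild-type 3. Genotype with random hexamers gave 4 without wild-type 2 and 5 without wild-type 1 or 3. The interaction gave 2 without wild-type 3. Priming in wild type gave 32, 41, 67, 76 and 101 without wild-type 2, wild-type 4, wild-type 1, paps1-1 2 and paps1-1 1. Priming in paps1-1 gave 16, 19 and 21 without paps1-1 3, 4 and 2, and 215 without wild-type 3.

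Replicate numbers did not pair the genotypes in a consistent way, although 4 numbers are too few to exclude a shared batch. Deviations of same-numbered libraries correlated at 0.27, -0.02, 0.05 and -0.09 with oligo(dT) and at 0.54, 0.32, -0.03 and -0.24 with random hexamers, and 1 of 4 and 2 of 4 correlated best with their own number. A replicate block gave 4 genes with oligo(dT) and 15 with random hexamers. Without the block of RNA sample (no replicate block), priming gave 16 genes in paps1-1.

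Of the list tests, 14 of 73 passed with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.347. For the heat shock list with random hexamers the median stayed at -1.59 under that choice, with no call, leaving out 1 replicate gave -1.83 to -1.14, and leaving out paps1-1 2 and 3 gave -1.24. The correlation of genotype effects was 0.116 to 0.361 when 1 replicate was left out, the lowest without wild-type replicate 1. A window around PAPS1 of double width held 1 of 9 genes (Fisher's exact p = 0.588), and 1 of the 37 genes of the DESeq2 Wald test lay in the window.

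The median over all genes moved with the scaling. DESeq2 size factors moved it from 0.43 to 0.81 and from 0.38 to 0.53 between genotypes, from 0.97 to 0.66 for the interaction, and from -3.92 to -3.16 and from -2.53 to -2.08 for priming. Upper-quartile factors could not be computed for the oligo(dT) genotype fit or the fit over 16 libraries. Leaving out organelle genes was not run, since no such gene was analysed here. The limit of a count of 0 was 42.9 CPM in wild-type oligo(dT) 3, 0.669 to 5.28 CPM in the other oligo(dT) libraries and 0.567 to 4.77 CPM in the random-hexamer libraries.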

Other observations

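The tests of genes near one another, of transcripts lost in single libraries, of the heat shock ratio and share within libraries and between priming methods, of 1 aberrant library, of the smallest p of any list and of length, with its set of genes, and the splits for counts of genes, for lists between priming methods and for the correlation of genotype effects, were chosen after the result was seen. Transcripts of mRNA turnover lay toward the random-hexamer side in wild type, as did most genes. Of 24 decay genes, 22 had a negative log2 ratio of oligo(dT) to random hexamers, none passed the threshold over all genes and 4 did when adjusted over the list alone (camera adjusted p = 0.140, list median -5.28 against -3.92 over all genes). DCP5 (AT1G26110), a decapping factor, and XRN4 (AT1G54490), a cytoplasmic exonuclease, had no count with oligo(dT) and averaged 49.6 ± 35.1 and 57.4 ± 34.1 CPM with random hexamers (SD, n = 4). Of the 7 cytoplasmic poly(A)-binding protein genes 7 were negative, and PAB4 (AT2G23350) had no count with oligo(dT) and 105 ± 46.7 CPM with random hexamers, past the threshold when adjusted over the list alone. The median of that list, -2.91, lay above that of all genes although camera ranked it lower (adjusted p = 0.238). Of the 3-prime end processing genes 24 of 26 were negative and none passed (median -3.89, adjusted p = 0.502), among them CSTF64 (AT1G71800), a cleavage factor subunit, at no count and 67.5 ± 19.9 CPM.

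In paps1-1 the decay list had 23 of 24 negative values, the poly(A)-binding proteins 7 of 7 and the 3-prime end genes 23 of 26, with no gene past the threshold and camera adjusted p of 0.159, 0.358 and 0.478. Their medians were -3.15, -3.29 and -2.93, against -2.53 over all genes. PAB4 averaged 13.6 ± 16.9 CPM with oligo(dT) and 86.6 ± 36.3 CPM with random hexamers. In the heat shock list 12 of 14 values were negative in paps1-1 and 14 of 14 in wild type, with 3 and 4 past the threshold when adjusted over the list alone. HSP101 averaged 72.9 ± 53.2 against 569 ± 193 CPM in paps1-1 and 215 ± 221 against 1816 ± 817 CPM in wild type. DCP5 and CSTF64 had log2 ratios of -2.80 and -3.30 in paps1-1 (edgeR adjusted p = 0.591 and 0.673), and no interaction of a single gene passed the threshold.

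Other splits of the same libraries were counted for each comparison. As many genes were called in 6 of 35 splits for genotype with oligo(dT), where the real value and the highest other were both 1, so chance cannot be excluded for the number of genes. The count says nothing of which gene, and AT1G34095 lay at 2737 to 4688 CPM in the 8 wild-type libraries and at 0 to 205 CPM in the 8 paps1-1 libraries of both priming methods. AT1G34095 was picked for its difference in the oligo(dT) libraries, and the random-hexamer libraries come from the same 8 RNA samples. Its separation is therefore no independent evidence against chance. For genotype with random hexamers 1 of 35 splits, the real one, gave as many, with 9 genes against at most 1 elsewhere. That is the smallest share that 35 splits can give, and it was not adjusted for the other counts tested here. The 9 genes form 6 groups when neighbouring genes are counted once, so they are not 9 independent events. The share argues against chance for this count alone and does not exclude it. For the interaction, with 0 genes, 35 of 35 splits gave as many by necessity, the highest other giving 1, so this count says nothing about chance. Libraries of the 2 priming methods are paired by RNA sample, and 8 splits part all 4 pairs, too few for a share under 0.125. Among these, for priming in wild type and in paps1-1, 1 of 8 splits, the real one, gave as many genes, with 163 against at most 2 and 40 against at most 2. The 24 splits that part 2 pairs, some of which repeat one another in a fit with the RNA sample as a block, gave at most 9 and 10. The correlation of genotype effects, 0.322, was reached in 8 of 35 splits, the highest other being 0.480. Lists called by camera were as many in 19 of 35 splits for genotype with oligo(dT) (1 list, highest other 4), 7 of 35 with random hexamers (8, highest other 10) and 8 of 35 for the interaction (2, highest other 3). For these list counts and the correlation chance cannot be excluded. For priming 5 of the 8 splits called as many lists in wild type (2, highest other 3) and 5 of 8 in paps1-1 (1, highest other 1), again too few for a share under 0.05. The camera p of the heat shock list with random hexamers, 3.48e-15, was reached in 1 of 35 splits, the real one, with 3.04e-10 as the smallest elsewhere, which concerns that list alone. The smallest p of any of the 15 lists was as small in 7 of 35 splits, down to 2.90e-21, so over all lists chance cannot be excluded.

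The first pattern is the set of 9 genes between genotypes with random hexamers, most of them close to all-or-none. That these are transcripts lost while single libraries were made is argued against for the 9 as a set, since in the oligo(dT) libraries of the same RNA they differed in the direction of their call by a mean of 2.71 on the log2 scale, with neighbouring genes counted once, which was the largest of 70 relabellings (highest other 2.18, one-sided exact permutation p = 0.0143, the smallest possible), and AT3G43681 had no count in the 8 wild-type libraries and at least 20 counts in each of the 8 paps1-1 libraries. In the oligo(dT) libraries 7 genes differed in the direction of their call by more than 1, and the genotype groups of 6 of these overlapped. Apart from AT3G43681, the separation of single genes was therefore not repeated there. For AT3G32925, with 1 oligo(dT) count in all, and FAF1, with an oligo(dT) difference of -0.09, the values of the single gene do not decide, and loss before the RNA was split is not covered. Of the 9 genes, 4 lay within 500 locus numbers of another, against a mean of 0.282 in 10000 random draws (one-sided permutation p = 0.00550), so linked sequence differences from the reference carried by 1 genotype may be a source, although neighbouring paralogs and overlapping genes with a shared response would give the same count. An effect of the paps1-1 allele itself was not tested and stays open.

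The second pattern is the lower level of heat shock transcripts in paps1-1 with random hexamers, for which chance is not excluded once all lists are counted. A common loss of pollen transcripts through scaling or RNA of other tissue is argued against for summed counts. The log2 ratio of summed heat shock to summed pollen cell wall counts within a library differed by -1.11 without overlap (exact two-sided permutation p = 0.0286, the smallest possible). Abundant members weigh most in such sums. The mean log2 CPM of the heat shock members, which weighs genes equally, overlapped between genotypes (exact two-sided permutation p = 0.114). An origin in 1 aberrant library is argued against because the list median stayed at -1.14 or below without any single library. With oligo(dT) the ratio differed by 0.0994 (exact p = 0.886), while the share of gene counts was lower in paps1-1 there too for heat shock genes (0.288% against 0.479%, exact p = 0.0571) and for cell wall genes (7.84% against 12.7%, exact p = 0.0857). The random-hexamer minus oligo(dT) ratio was 1.09 ± 0.352 in paps1-1 and 2.29 ± 0.635 in wild type (SD, n = 4, exact two-sided permutation p = 0.0286). That of the log2 heat shock share was 0.78 ± 0.30 and 1.55 ± 0.38 (exact two-sided permutation p = 0.0286). The genotype difference was thus smaller with oligo(dT) in both measures. There the ratio showed no lower value in paps1-1, and the heat shock share was lower alongside the cell wall share. A common loss is therefore argued against with random hexamers only, and for summed counts only. The list's interaction did not pass (11 of 14 positive, camera adjusted p = 0.240). The day or temperature of growth and collection is not given by the labels, and it and the genotype stay open as untested explanations.

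The third pattern is a lower oligo(dT) to random-hexamer ratio of longer transcripts. Among the 500 genes of highest mean CPM, 499 of which had an annotated transcript length, Spearman's rho across genes between length and log2 ratio was negative in 8 of 8 RNA samples, from -0.591 to -0.153 with a median of -0.513, where genes are not independent replicates. Low counts of long transcripts are argued against, since the median rho was -0.476 in the 250 of these genes with the higher mean. A difference between genotypes cannot be told apart from the spread, with rho at -0.538 ± 0.0597 in paps1-1 and -0.422 ± 0.184 in wild type (SD, n = 4, exact two-sided permutation p = 0.286), the value of wild-type sample 3 being -0.153. Priming from the 3-prime end could give such a trend, but no test of read position was possible with counts per gene.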
